A study of Homo sapiens with 12 samples.

How the data were processed

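Messenger RNA levels were measured by RNA sequencing in 12 libraries from MDA-MB-231, a human triple-negative breast cancer cell line. Per the labels, dishes plated in triplicate were treated for 24 h with vehicle (DMSO and water), 2 µM BITC, 1 µM ZA, or both compounds together, and each of these 4 groups holds 3 libraries. The labels give the compounds only as abbreviations; from knowledge of the study, BITC was read as benzyl isothiocyanate and ZA as zoledronic acid. Cells were harvested with trypsin, total RNA was purified on RNeasy columns and libraries were made with a standard Illumina protocol, per the labels' protocols. Beyond the dishes in triplicate, nothing says that the 3 libraries of a group came from separate cultures, so the p-values may measure only the spread between these samples, which may be technical.

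The submitters' processing notes name HISAT2 for alignment, DESeq2 1.20.0 and the human build GRCh38 (hg38). The read counter, the annotation release and the strand setting are not given in the sources used here. Reads from overlapping genes, antisense partners, paralogs and pseudogenes can therefore not be told apart with certainty. The deposited tables comprise 6 pairwise comparisons and a table of FPKM values. Per the file headers, each comparison table holds raw read counts per gene for 6 libraries, which the authors did not pool or normalize. The same tables hold each count divided by a size factor per library, a normalized signal that the authors estimated within the 6 libraries of a table, and its mean per group. The authors' log2 fold changes, p-values and adjusted p-values stand beside them, per the file headers. FPKM values, which scale fragments by gene length and library total, were deposited for 58735 genes, with a scaling total that is not given in the sources used here. Coordinates are those of the deposited tables, on GRCh38.

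The raw counts of the 6 tables were joined by Ensembl gene identifier. The joined table held 27412 genes with 0 conflicting counts. A table left out genes without reads, and the 4593 values missing for this reason had an FPKM of 0 in every case and were entered as 0. Of the genes with FPKM values, 2813 lay outside the joined set with a value above 0, and these were not tested. The totals ran from 15874857 to 17375664 counts per library. A symbol shared by several identifiers occurred for 266 identifiers and 47 symbols, and genes were therefore kept apart by identifier. No 2 libraries of a group agreed within sampling noise: over 11451 genes the chi-square per gene between replicates was 2.29 to 3.97, apart from ZA library 1 against ZA libraries 2 (16.9) and 3 (15.1).

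Counts were tested with edgeR 4.0.16 in R 4.3.3, with trimmed mean of M values normalization, the filterByExpr filter and the robust quasi-likelihood F test. All 12 libraries entered 1 model of the 4 groups without a replicate block, which leaves 8 residual degrees of freedom and a spread per gene shared by all groups. The filter kept 14950 genes, which held 99.9% of the counts, and the common biological coefficient of variation was 0.0607. The 6 pairwise comparisons and the interaction, which is the log2 change under both compounds minus the sum of the changes under each, were tested two-sided. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM after normalization, as mean ± SD with n = 3 per group.

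In counts simulated from the means and library sizes of these samples, 200 of the 14950 genes were changed, 50 at each of 4 fold sizes. For BITC against vehicle the test recovered 34% of genes changed 1.25-fold, 74% at 1.5-fold, 96% at 2-fold and 96% at 3-fold, with 7.98% false calls. The shares were 48, 70, 96 and 98% for ZA against vehicle (3.70% false) and 40, 78, 96 and 98% for BITC+ZA against vehicle (2.50% false). For the interaction they were 22, 60, 72 and 88% (6.20% false). Changes under 1.5-fold were thus often missed at this depth and number of libraries.

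In all, 36 gene lists were written, with 597 symbols of which 578 matched and 538 were tested, and 34 lists had at least 3 tested members. They were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, adjusted over the 34 lists within a comparison. With the estimated correlation, 5 of 12 camera calls held for BITC against vehicle, 0 of 14 for ZA against vehicle, 3 of 10 for BITC+ZA against vehicle, 0 of 4 for BITC+ZA against BITC, 6 of 13 for BITC+ZA against ZA, 3 of 15 for ZA against BITC and 0 of 7 for the interaction. Fry, which tests whether the members move one way on balance and compares them with no other genes, called 14, 10, 15, 12, 21, 19 and 13 lists in that order. Beside each list, the members called over all genes are counted with those called when adjusted over the list alone.

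Genes were named by rule. Against vehicle, the 10 highest and 10 lowest log2 fold changes were taken among called protein-coding genes without overlap between the groups and with a mean FPKM of at least 1 in the higher group. The first 5 each way were taken for the other comparisons and for the interaction, there without the overlap condition. For each list with at least 2 called members or a camera call, the 3 members with the smallest p were added. FDPS, HMGCS1, HMOX1, NQO1 and GCLM were named in every comparison whatever their values. Many genes and lists that the rule also names are not reported here. The rule gives 520 values of genes, of which the text prints 161, and which genes and lists it prints was chosen after the values had been seen. The test, the groups, the lists, the rule and 9 alternative settings, besides leaving out each of the 12 libraries in turn, were fixed before the data were examined.

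Those alternatives were median-of-ratios size factors, no filter on low counts, an FPKM of at least 5 in 3 libraries, the DESeq2 1.42.0 Wald test, limma on log2(FPKM + 1) and on log2(FPKM + 0.1), a fit to the libraries of the 2 groups only, the replicate number as a block, and protein-coding genes only. After the data had been seen, 2 more were added: a correction that removed each library's trend on GC content and exon length as an offset, and the same without ZA library 1. GC content was computed from GENCODE transcript sequences on GRCh38, matched by Ensembl identifier, for 27397 of the 27412 genes. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.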

Results

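The study measured the transcriptome of MDA-MB-231 cells after 24 h with vehicle, 2 µM BITC, 1 µM ZA, or both. BITC (benzyl isothiocyanate) is an electrophilic compound from cruciferous plants, and ZA (zoledronic acid) is a nitrogen-containing bisphosphonate used against bone metastasis that inhibits farnesyl diphosphate synthase, the enzyme encoded by FDPS. Each of the 4 groups had 3 libraries, named here by group and number, and the totals lay between 15874857 and 17375664 counts. Of 27412 genes with counts, 14950 were tested. Log2 fold changes are given with their standard errors (SE), adjusted p-values are those of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment or, for gene lists, of camera, and levels are CPM as mean ± SD with n = 3.

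The libraries differed in their trends on GC content. Across genes, the rank correlation of a library's deviation from the mean of all libraries with GC content was −0.507 in ZA library 1 but 0.557 and 0.599 in ZA libraries 2 and 3. It was negative in every vehicle and BITC library, from −0.611 to −0.0279, and positive in every BITC+ZA library, from 0.312 to 0.488. ZA library 1 also lay apart from the others of its group: the correlation of its deviations with those of ZA libraries 2 and 3 was −0.217 and −0.288, against 0.529 between these 2. Results involving ZA therefore rest on libraries that differed from each other more than those of any other group.

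**Figure D1:**
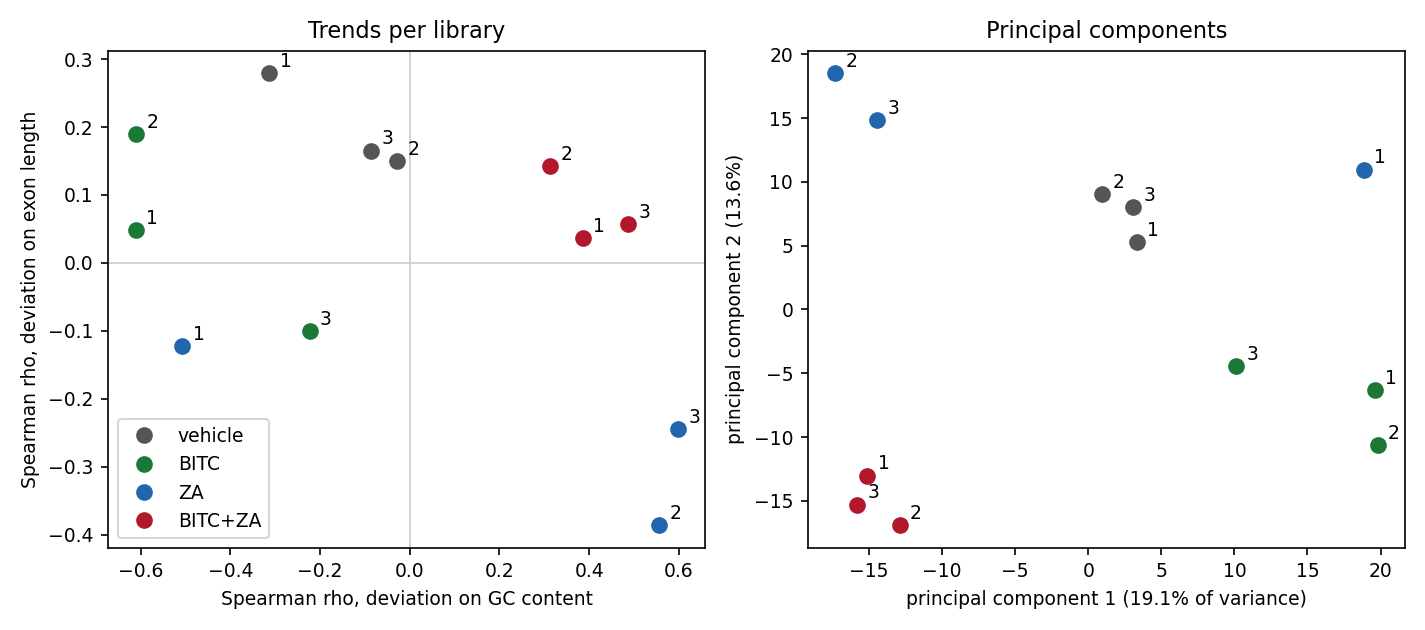
Each point is 1 library, coloured by group. The left panel plots the rank correlation across genes of the library's log2 deviation with GC content (x axis) against that with exon length (y axis), and the right panel plots principal component 1 (19.1% of variance) against component 2 (13.6%). ZA library 1 lies away from ZA libraries 2 and 3, with a correlation with GC content of −0.507 against 0.557 and 0.599.

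The comparison of BITC with vehicle asked what the isothiocyanate alone changed. NQO1, a quinone reductase and a textbook target of the oxidative stress factor NRF2 (chromosome 16, 69706996 to 69726951, minus strand), rose from 249.8 ± 7.87 to 436 ± 2.33 CPM (log2 fold change 0.80, SE 0.04, adjusted p = 7.38e-13). SLC7A11, the cystine importer of glutathione synthesis, rose from 121 ± 0.886 to 205 ± 11.1 CPM (0.77, SE 0.06, adjusted p = 8.94e-10), and FTL, the ferritin light chain, from 2146 ± 46.2 to 3576 ± 91.7 CPM (0.74, SE 0.04, adjusted p = 7.38e-13). CXCL8, which encodes the chemokine interleukin 8, rose from 19.3 ± 0.839 to 34.4 ± 1.40 CPM (0.83, SE 0.09, adjusted p = 1.64e-06). CEMIP, a hyaluronan-degrading factor, fell from 95.7 ± 1.85 to 56.6 ± 0.428 CPM (−0.76, SE 0.07, adjusted p = 5.71e-08). INHBA, the activin A subunit, fell from 23.7 ± 1.83 to 14.9 ± 1.75 CPM (−0.67, SE 0.10, adjusted p = 0.000124). FTL has many processed pseudogenes, with which its counts may be shared.

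Of the 26 NRF2 targets tested, 18 were called higher and 0 lower, or 25 adjusted over the list alone, and the list was higher than other genes (adjusted p = 1.41e-91, and 1.48e-05 with an estimated correlation). Besides the genes above, GCLM, a subunit of the rate-limiting enzyme of glutathione synthesis, rose from 191 ± 4.17 to 256 ± 12.1 CPM (0.43, SE 0.05, adjusted p = 5.07e-06). PIR (0.97, SE 0.15, adjusted p = 0.000249), AKR1C3 (0.82, SE 0.11, adjusted p = 3.32e-05) and TRIM16L (0.74, SE 0.07, adjusted p = 5.04e-08) also rose, although AKR1C3 and TRIM16L have close paralogs that could share reads. HMOX1, heme oxygenase and another NRF2 target, was at 15.5 ± 2.64 and 16.9 ± 1.94 CPM and was not called (0.12, SE 0.14, adjusted p = 0.706). Outside the list, PANX2 (0.80, adjusted p = 0.00594) and TMEM71 (0.73, adjusted p = 9.13e-05) rose, and RTN4R (−0.86, adjusted p = 0.00992), PPL (−0.71, adjusted p = 0.000249) and LLGL2 (−0.58, adjusted p = 0.0105) fell. The call of PANX2 was lost without vehicle library 1 (adjusted p = 0.0601), that of RTN4R without vehicle library 1 (0.103) or BITC library 2 (0.103), and that of LLGL2 without vehicle library 2 (0.103) or BITC library 1 (0.118).

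Lipid synthesis lists were lower after BITC. Among 9 genes of fatty acid synthesis 3 were called lower, or 6 over the list alone (adjusted p = 1.43e-06, and 0.0259 by estimated correlation), led by SCD, the stearoyl-CoA desaturase, which fell from 504 ± 12.4 to 395 ± 11.5 CPM (−0.35, SE 0.04, adjusted p = 1.54e-05). Of 20 mevalonate and sterol synthesis enzymes 2 were called lower, or 3 over the list alone (adjusted p = 4.48e-05, and 0.0132 by estimated correlation). DHCR7, a late enzyme of sterol synthesis, was among them (−0.34, adjusted p = 0.00445). FDPS (−0.13, adjusted p = 0.339) and HMGCS1 (−0.14, adjusted p = 0.291) were not called. After GC and length correction HMGCS1 was called lower (−0.21, adjusted p = 0.0318). DHCR7 was no longer called without vehicle library 2 (adjusted p = 0.0614) or BITC library 1 (0.058).

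Other lists were called as well. Of 20 genes of G2/M and mitosis 3 were called higher, or 9 over the list alone (adjusted p = 5.09e-06, but 0.106 by estimated correlation), including CCNB1, the mitotic cyclin (0.24, adjusted p = 0.0072). Of 18 collagens and laminins 1 was called higher and 5 lower, or 1 and 8 over the list alone (adjusted p = 0.000233, but 0.159 by estimated correlation), with COL5A1 among those that fell (−0.33, adjusted p = 0.00259). The epithelial keratin gene KRT8 fell (−0.26, adjusted p = 0.00445), the single call among 8 epithelial markers, against 5 over the list alone (adjusted p = 0.00384, but 0.221 by estimated correlation). Of 5 targets of the aryl hydrocarbon receptor AHR 2 were called higher, NQO1 and the cytochrome gene CYP1B1 (0.23, adjusted p = 0.0153), or 4 over the list alone (adjusted p = 8.8e-14, and 0.000752 by estimated correlation). NQO1 belongs to the NRF2 list too. Among 17 factors of bone metastasis 2 were called higher, CXCL8 and the interleukin gene IL11 (0.53, SE 0.09, adjusted p = 0.000679), or 3 over the list alone (adjusted p = 0.0125, but 0.0717 by estimated correlation). CCNB1 was lost without vehicle library 2 (adjusted p = 0.0646) or BITC library 1 (0.0678), COL5A1 without BITC library 1 (0.0539), and KRT8 without vehicle library 3 (0.0614), BITC library 1 (0.0663) or BITC library 2 (0.0561). CYP1B1 was lost without vehicle library 1 (0.068), 2 (0.122) or 3 (0.0584) and without BITC library 1 (0.123) or 2 (0.0949).

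In total BITC changed 266 of the 14950 genes, 116 higher and 150 lower, with a median fold size of 1.26. As a sign of RNA quality, the mitochondrial share was 3.94 ± 0.136% against 3.55 ± 0.061% without overlap, and the lists of 13 mitochondrially encoded transcripts (adjusted p = 0.000235, but 0.463 by estimated correlation) and 9 histone transcripts (0.00125, and 0.0376) were called higher with 0 members called. A fold of at least 2 was reached by 6 of the genes called higher and 1 called lower. The 2 groups did not overlap for 265 of the called genes, and for 25.2% of all genes tested, where chance gives 10%. The number called was 118, 112 and 126 without vehicle libraries 1, 2 and 3, and 102 and 137 without BITC libraries 1 and 2. It was 1496 without ZA library 1, which enters through the shared estimate of spread.

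**Figure D2:**
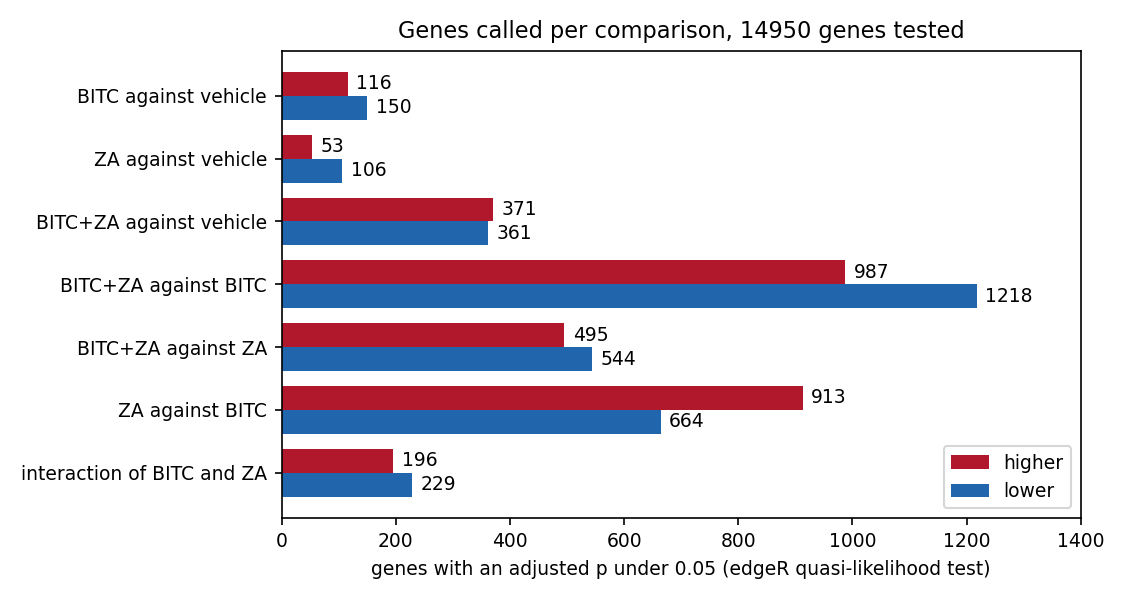
Bars give the number of genes called higher (up) and lower (down) in each of the 7 comparisons at an adjusted p below 0.05, of 14950 tested. BITC+ZA against BITC has the most calls and ZA against vehicle the fewest.

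ZA was compared with vehicle to find what the bisphosphonate alone changed. RHOB, a small GTPase that is itself prenylated (chromosome 2, 20447074 to 20449445, plus strand), rose from 22.4 ± 0.921 to 37.9 ± 1.04 CPM (0.76, SE 0.07, adjusted p = 1.83e-06). CXCL8 rose from 19.3 ± 0.839 to 27.5 ± 3.43 CPM (0.51, SE 0.09, adjusted p = 0.00738), as did TOMM7, of the mitochondrial import complex (0.57, SE 0.10, adjusted p = 0.00738), TPM2, a tropomyosin (0.48, SE 0.10, adjusted p = 0.0221), and RABAC1 (0.80, SE 0.20, adjusted p = 0.0465). RAPH1, an actin regulator of the lamellipodium, fell from 35.9 ± 3.18 to 23.4 ± 4.04 CPM (−0.62, SE 0.11, adjusted p = 0.00738). MICAL3 (−0.49, adjusted p = 0.00738), ZFHX3 (−0.42, adjusted p = 0.00806), PRRC2C (−0.42, adjusted p = 0.00738), SOGA1 (−0.37, adjusted p = 0.00322) and USP34 (−0.35, adjusted p = 0.00322) also fell. Genes called lower had a median exon length of 12510.5 bases, against 2155 for those called higher and 4617.5 for all genes tested. Without vehicle library 1 RHOB kept its call, and those of SOGA1, USP34, PRRC2C, MICAL3 and TOMM7 (adjusted p = 0.0625 each), CXCL8 and RAPH1 (0.0806 each), ZFHX3 (0.0815), TPM2 (0.216) and RABAC1 (0.21) were lost. TOMM7 was also lost without vehicle library 3 (0.0869) or ZA library 2 (0.0746), MICAL3 without vehicle library 2 (0.0529) or ZA library 2 (0.0605), and ZFHX3 without vehicle library 2 (0.0684) or ZA library 2 (0.0662). TPM2 was lost without vehicle library 3 (0.113), ZA library 2 (0.168) or ZA library 3 (0.0637), and RABAC1 without any library other than ZA library 1 (0.0508 to 0.219) and after GC and length correction (0.62, adjusted p = 0.0554).

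None of the 20 mevalonate and sterol enzymes was called, by either adjustment, although the list as a whole was higher at the preset correlation (adjusted p = 0.0267, but 0.193 by estimated correlation). That list call was lost without vehicle library 3 (adjusted p = 0.0562), ZA library 2 (0.0814) or ZA library 3 (0.0579). FDPS was at 64.9 ± 1.43 CPM in vehicle and 69.0 ± 4.81 in ZA (0.09, SE 0.06, adjusted p = 0.546). HMGCS1 (0.09, adjusted p = 0.549) and the NRF2 targets NQO1 (0.03, adjusted p = 0.795), GCLM (−0.03, adjusted p = 0.866) and HMOX1 (−0.01, adjusted p = 0.977) were not called either. Of the 26 NRF2 targets 0 were called by either adjustment (adjusted p = 0.55).

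Of 16 targets of the growth regulators YAP and TEAD 3 were called lower, or 1 higher and 5 lower over the list alone (adjusted p = 0.0363, but 0.193 by estimated correlation), among them PTPN14 (−0.25, adjusted p = 0.0077), which is known to restrain YAP. The proliferation marker MKI67 fell from 702 ± 5.56 to 582 ± 55.6 CPM (−0.27, SE 0.06, adjusted p = 0.0176), and LAMA3, a laminin chain, from 58.3 ± 1.57 to 46.2 ± 1.76 CPM (−0.33, SE 0.07, adjusted p = 0.0176). Of 20 AP-1 and immediate early genes 0 were called, or 3 higher over the list alone (adjusted p = 0.0363, but 0.37 by estimated correlation). Lists taken as measures of RNA quality moved with this comparison. Of 39 ribosomal protein transcripts 2 were called higher, or 10 over the list alone (adjusted p = 2.07e-11, but 0.193 by estimated correlation). Of 13 mitochondrially encoded transcripts 2 were called higher, or 7 over the list alone (adjusted p = 1.05e-08, but 0.236 by estimated correlation). The mitochondrial share was 4.25 ± 0.604% against 3.55 ± 0.061% without overlap. The call of the YAP list was lost without vehicle library 2 (adjusted p = 0.058), vehicle library 3 (0.0606), ZA library 1 (0.104) or ZA library 3 (0.0579), and that of the AP-1 list without vehicle library 3 (0.0663), ZA library 2 (0.187) or ZA library 3 (0.161). After GC and length correction the AP-1 list had no call and the opposite direction (0.716). PTPN14 was lost without vehicle libraries 1 (0.0806) or 3 (0.0628) or ZA library 2 (0.0636). MKI67 and LAMA3 were lost without vehicle library 1 (0.101 and 0.146), 2 (0.0742 and 0.0749) or 3 (0.0971 and 0.089) or ZA library 2 (0.128 and 0.0847). MKI67 was also lost after GC and length correction (−0.17, adjusted p = 0.0883).

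In all, ZA changed 159 genes, 53 higher and 106 lower, with a median fold size of 1.204. The share higher was 33.3%, and 49.6% after GC and length correction without ZA library 1. Without ZA library 1 alone the majority turned, with 1399 higher and 1090 lower (56.2% higher), and without ZA library 3 the share was 22.7%. On FPKM values limma called 1 gene on log2(FPKM + 1) and 6 on log2(FPKM + 0.1), of which 100% and 50% were higher. Of the called genes 157 did not overlap between the groups, as did 16.4% of all genes tested, where chance gives 10%. The number called was 1, 30 and 27 without vehicle libraries 1, 2 and 3, 89 without BITC library 1, 2489 without ZA library 1, 16 without ZA library 2, and 84, 80 and 83 without BITC+ZA libraries 1, 2 and 3.

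**Figure D3:**
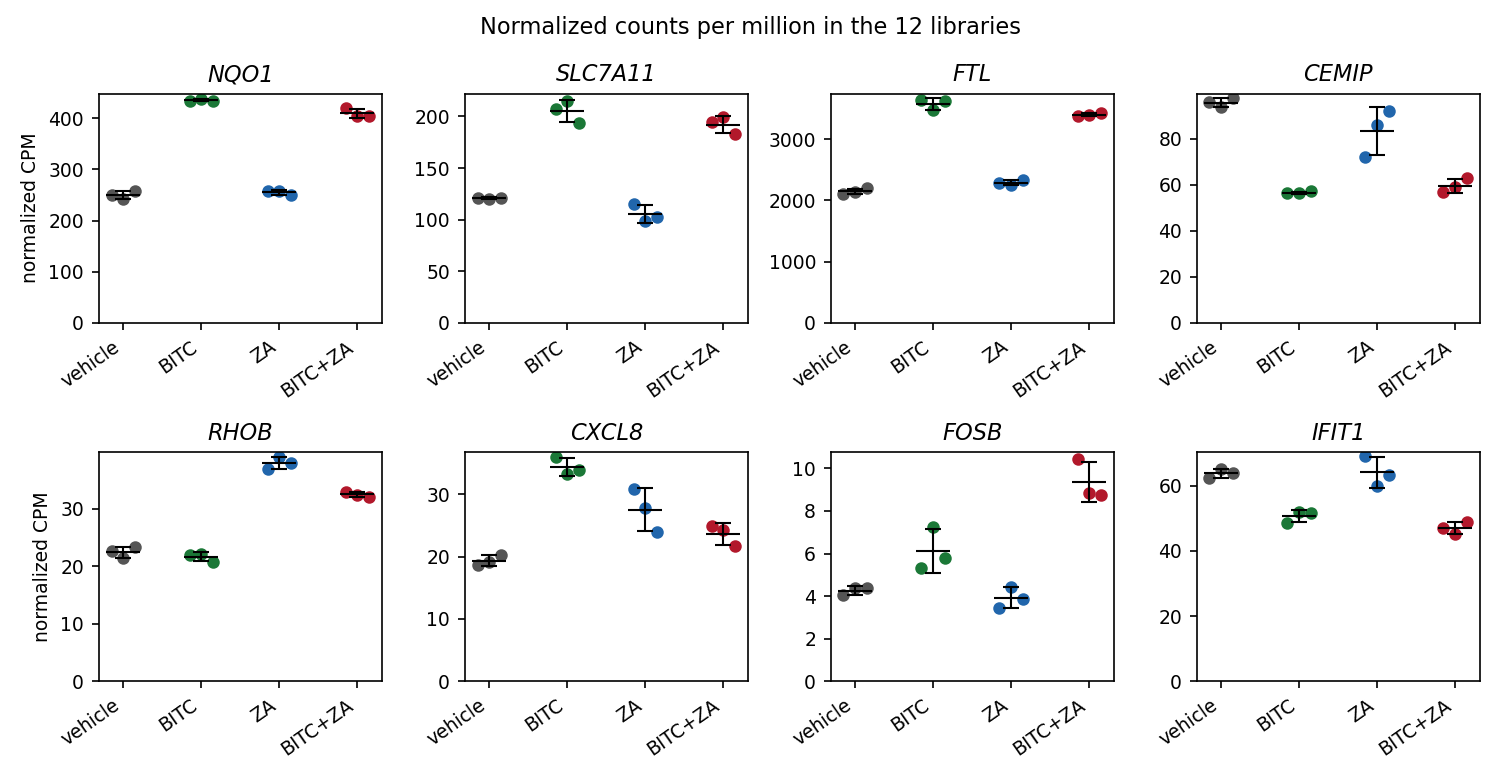
Points are single libraries and bars the group means with SD (n = 3) in CPM for 8 genes in the 4 groups. NQO1, SLC7A11 and FTL are high in both groups with BITC, RHOB in both groups with ZA, FOSB is highest in BITC+ZA (9.34 ± 0.929 CPM), and CXCL8 is highest with BITC alone (34.4 ± 1.40 CPM).

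BITC+ZA was compared with vehicle for the response to both compounds. FOSB, an immediate early transcription factor, rose from 4.26 ± 0.197 to 9.34 ± 0.929 CPM (1.13, SE 0.16, adjusted p = 5.23e-05), and FOS from 22.3 ± 1.18 to 32.1 ± 1.31 CPM (0.53, SE 0.09, adjusted p = 0.000548). NQO1 rose to 409.7 ± 8.38 CPM (0.71, SE 0.04, adjusted p = 1.29e-11) and FTL to 3398 ± 21.1 CPM (0.66, SE 0.04, adjusted p = 1.29e-11). DDIT3, a stress-induced transcription factor, rose from 5.66 ± 0.444 to 9.30 ± 0.560 CPM (0.72, SE 0.15, adjusted p = 0.00525). CEMIP fell to 59.5 ± 3.05 CPM (−0.69, SE 0.07, adjusted p = 3.5e-07), the oxytocin receptor gene OXTR from 23.5 ± 0.934 to 15.3 ± 1.42 CPM (−0.62, SE 0.09, adjusted p = 0.000141), and INHBA to 16.3 ± 0.423 CPM (−0.54, SE 0.10, adjusted p = 0.00101).

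Of the 26 NRF2 targets 22 were called higher and 0 lower, or 24 over the list alone (adjusted p = 2.32e-62, and 6.23e-05 by estimated correlation). TRIM16L (0.82, SE 0.07, adjusted p = 1.1e-08), PIR (0.85, SE 0.15, adjusted p = 0.000924), SRXN1, a sulfiredoxin (0.83, SE 0.17, adjusted p = 0.00356), OSGIN1 (0.88, SE 0.18, adjusted p = 0.00824), GCLM (0.25, SE 0.05, adjusted p = 0.00251), and the autophagy receptor gene SQSTM1 (0.29, SE 0.05, adjusted p = 0.000481) were among the genes that rose. HMOX1 rose from 15.5 ± 2.64 to 21.4 ± 2.15 CPM (0.47, SE 0.13, adjusted p = 0.0425). FDPS (0.06, adjusted p = 0.644) and HMGCS1 (−0.07, adjusted p = 0.604) were not called. Of 5 AHR targets 1 was called higher, NQO1, or 2 over the list alone (adjusted p = 3.32e-05, and 0.0259 by estimated correlation). The largest increases by the naming rule also included RAB3A (1.27, SE 0.32, adjusted p = 0.0176), RPL36A (0.96, SE 0.16, adjusted p = 0.000634), which shares sequence with a readthrough transcript and pseudogenes, and LY6G5B (0.88, SE 0.15, adjusted p = 0.000587). The call of HMOX1 was lost without vehicle library 1 (adjusted p = 0.097) or 3 (0.225), BITC library 1 (0.0639) or BITC+ZA library 1 (0.109), 2 (0.0683) or 3 (0.223). OSGIN1 was lost without vehicle library 1 (0.0609) or 2 (0.055) or BITC+ZA library 3 (0.0551), and RAB3A without vehicle library 1 (0.086) or 3 (0.0646) or BITC+ZA library 2 (0.0634) or 3 (0.0666).

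Of 20 AP-1 and immediate early genes 7 were called higher, or 11 over the list alone (adjusted p = 1.47e-08, but 0.0711 by estimated correlation). VEGFA, the endothelial growth factor gene, rose (0.33, SE 0.05, adjusted p = 0.000482). Of 5 metallothionein and zinc export genes 3 were called lower by either adjustment (adjusted p = 0.000356, and 0.0376 by estimated correlation): MT2A, from 514 ± 25.2 to 436 ± 26.5 CPM (−0.24, SE 0.05, adjusted p = 0.00438), MT1E (−0.42, SE 0.10, adjusted p = 0.038) and the zinc exporter gene SLC30A1 (−0.33, SE 0.06, adjusted p = 0.00107). The metallothionein genes are near-identical copies in part, so single members are uncertain. Of 19 interferon-stimulated genes 3 were called lower, or 4 over the list alone (adjusted p = 0.00867, but 0.0825 by estimated correlation, and 0.0706 with the preset correlation over genes with an FPKM of at least 5). IFIT1 fell from 63.8 ± 1.47 to 46.9 ± 1.86 CPM (−0.44, SE 0.07, adjusted p = 0.000114) and IFIT3 from 111 ± 1.23 to 84.3 ± 2.15 CPM (−0.39, SE 0.07, adjusted p = 0.000512). Of 13 mesenchymal markers 2 were called lower, or 4 over the list alone (adjusted p = 0.0346, but 0.0991 by estimated correlation), with the matrix protein gene THBS1 falling from 2864 ± 9.83 to 2296 ± 44.6 CPM (−0.32, SE 0.04, adjusted p = 2.8e-05). The call of that list was lost without vehicle library 3 (adjusted p = 0.06) or BITC+ZA library 1 (0.127) or 2 (0.0605). DHRS3, a retinaldehyde reductase (−0.77, SE 0.21, adjusted p = 0.0273), and RTN4R (−0.70, SE 0.18, adjusted p = 0.0214) fell too. MT1E was no longer called without vehicle library 2 or 3 (adjusted p = 0.101 each), BITC library 2 (0.051) or BITC+ZA library 1 (0.0833), 2 (0.0977) or 3 (0.102), nor after GC and length correction (−0.48, adjusted p = 0.0881). DHRS3 was lost without vehicle library 2 (0.213) or BITC+ZA library 1 (0.0574), 2 (0.0716) or 3 (0.149), and RTN4R without vehicle library 1 (0.146) or BITC+ZA library 1 (0.107) or 2 (0.0732).

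Mitochondrially encoded transcripts made up 4.83 ± 0.0836% of the counts in BITC+ZA and 3.55 ± 0.061% in vehicle, and 8 of 13 were called higher, or 11 over the list alone (adjusted p = 9.53e-18, but 0.0991 by estimated correlation). MT-ATP6 rose from 2834 ± 74.2 to 4072 ± 112 CPM (0.52, SE 0.07, adjusted p = 0.000455) and MT-CO3 from 3985 ± 67.4 to 5087 ± 92.1 CPM (0.35, SE 0.04, adjusted p = 1.47e-05). The lists of ribosomal protein transcripts (lower, adjusted p = 0.022, but 0.516 by estimated correlation) and histone transcripts (higher, 0.0312, but 0.0991) were called with 0 members called. The first was lost without vehicle library 2 (0.0619) or 3 (0.089), and the second without vehicle library 1 (0.0576), ZA library 1 (0.0582) or BITC+ZA library 2 (0.0735) and after GC and length correction (0.137). In all, 732 genes were called, 371 higher and 361 lower, with a median fold size of 1.24, and 25 of those higher and 1 of those lower reached a fold of 2. Of the 2495 genes that do not code for protein 74 were called higher and 5 lower. The share higher among all calls was 50.7%, 31.8% and 30.8% by limma on log2(FPKM + 1) and log2(FPKM + 0.1), and 61.0% over genes with an FPKM of at least 5. All 732 called genes were without overlap between the groups, as were 32.8% of all genes tested, where chance gives 10%. The number called was 327, 404 and 348 without vehicle libraries 1, 2 and 3, 2234 without ZA library 1, and 391, 401 and 288 without BITC+ZA libraries 1, 2 and 3.

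Adding ZA to BITC was examined by comparing BITC+ZA with BITC. RHOB was higher with both compounds, at 32.5 ± 0.479 against 21.6 ± 0.780 CPM (0.58, SE 0.08, adjusted p = 6.71e-05), and so were the immediate early genes EGR1, at 140.0 ± 7.38 against 106.0 ± 1.49 CPM (0.40, SE 0.05, adjusted p = 6.71e-05), and IER2 (0.49, SE 0.08, adjusted p = 0.000825). The cytokine gene LIF (0.45, SE 0.08, adjusted p = 0.00176), FAM89B (1.43, SE 0.32, adjusted p = 0.00626) and TUBA3D (1.44, SE 0.38, adjusted p = 0.0142), which has near-identical tubulin paralogs, were also higher. CXCL8 was lower, at 23.6 ± 1.75 against 34.4 ± 1.40 CPM (−0.54, SE 0.09, adjusted p = 0.000947). FDPS, at 67.6 ± 3.02 against 59.3 ± 3.58 CPM, was higher (0.19, SE 0.06, adjusted p = 0.0477), and HMGCS1 (0.08, adjusted p = 0.461) was not called. TUBA3D was no longer called without BITC library 1 (adjusted p = 0.0782) or 2 (0.0698) or BITC+ZA library 1 (0.0527) or 2 (0.0542), and FAM89B without BITC library 1 (0.0532). FDPS was lost without vehicle library 1 (0.0658), 2 (0.0656) or 3 (0.066), BITC library 1 (0.207) or 2 (0.152), or BITC+ZA library 1 (0.06), 2 (0.147) or 3 (0.169), and after GC and length correction (0.13, adjusted p = 0.11). HMGCS1 was then called higher (0.21, adjusted p = 0.0174).

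Of 20 genes of G2/M and mitosis 1 was called higher and 10 lower, or 1 and 12 over the list alone (adjusted p = 4.6e-05, but 0.382 by estimated correlation). CCNB1 was lower, at 428 ± 7.43 against 506 ± 9.90 CPM (−0.24, SE 0.05, adjusted p = 0.00403), with the spindle checkpoint kinase gene TTK (−0.33, adjusted p = 0.00408) and the spindle assembly factor gene TPX2 (−0.23, adjusted p = 0.00534). Of 20 AP-1 and immediate early genes 7 were called higher, or 8 over the list alone (adjusted p = 4.6e-05, but 0.382 by estimated correlation). Of 18 heat shock genes 1 was called higher, HSPA1A (0.49, SE 0.10, adjusted p = 0.00337), a near copy of HSPA1B, and 7 lower, or 3 and 8 over the list alone, with no call for the list (adjusted p = 0.277). HSP90AA1 was at 3166 ± 30.8 against 3748 ± 63.2 CPM (−0.24, SE 0.04, adjusted p = 0.00228). Of 26 NRF2 targets 0 were called higher and 3 lower by either adjustment, with no call for the list (adjusted p = 0.474). GCLM was lower (−0.17, SE 0.05, adjusted p = 0.021), while NQO1 (−0.09, SE 0.04, adjusted p = 0.153) and HMOX1 (0.34, SE 0.13, adjusted p = 0.081) were not called. Without ZA library 1 both were called, NQO1 lower (adjusted p = 0.0342) and HMOX1 higher (0.00973). The call of GCLM was lost without BITC library 1 (adjusted p = 0.113) or 2 (0.1) or BITC+ZA library 2 (0.0795) or 3 (0.0903), and after GC and length correction (−0.03, adjusted p = 0.646).

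Among the measures of RNA quality, 4 of 13 mitochondrially encoded transcripts were called higher, or 8 higher and 1 lower over the list alone (adjusted p = 4.6e-05, but 0.485 by estimated correlation), and the mitochondrial share was 4.83 ± 0.0836% against 3.94 ± 0.136%. Of 39 ribosomal protein transcripts 2 were called higher and 12 lower, or 8 and 15 over the list alone (adjusted p = 0.00551, but 0.485 by estimated correlation, and 0.168 at the preset correlation without BITC library 3). RPS19, which has processed pseudogenes, was at 670.3 ± 3.71 against 820.4 ± 15.3 CPM (−0.29, SE 0.05, adjusted p = 0.000824). Altogether 2205 genes were called, 987 higher and 1218 lower, with a median fold size of 1.198. The share higher was 44.8%, and 27.2% and 27.0% by limma on the 2 FPKM scales. The majority turned over genes with an FPKM of at least 5 (1070 higher, 777 lower, 57.9% higher). GC and length correction called 1287 genes, of which 802 were among the 2205. The groups did not overlap for 2180 of these genes, and for 38.1% of all tested, where chance gives 10%. The number called was 525 and 791 without BITC libraries 1 and 2, 4116 without ZA library 1, and 1085, 1112 and 603 without BITC+ZA libraries 1, 2 and 3.

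Adding BITC to ZA was examined by comparing BITC+ZA with ZA, and NRF2 targets were among the genes that were higher. SLC7A11 was at 192 ± 8.40 against 105 ± 8.31 CPM (0.87, SE 0.06, adjusted p = 9.64e-11), NQO1 at 409.7 ± 8.38 against 255 ± 4.52 CPM (0.68, SE 0.04, adjusted p = 7.41e-11) and FTL at 3398 ± 21.1 against 2287 ± 43.4 CPM (0.57, SE 0.04, adjusted p = 1.7e-10). TRIM16L (0.82, SE 0.07, adjusted p = 8.93e-09), GCLM (0.28, SE 0.05, adjusted p = 0.000932) and HMOX1 (0.48, SE 0.13, adjusted p = 0.0302) were also higher. Of the 26 NRF2 targets 21 were called higher and 0 lower, or 22 over the list alone (adjusted p = 1.36e-54, and 8.65e-05 by estimated correlation). Of 5 AHR targets 2 were called higher by either adjustment (adjusted p = 2.32e-06, and 0.00882 by estimated correlation). FOSB was at 9.34 ± 0.929 against 3.92 ± 0.4998 CPM (1.249, SE 0.16, adjusted p = 2.54e-05). The call of HMOX1 was lost without BITC+ZA library 1 (adjusted p = 0.0773), 2 (0.0614) or 3 (0.174).

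Of 20 mevalonate and sterol enzymes 2 were called lower, or 4 over the list alone (adjusted p = 0.000753, and 0.0248 by estimated correlation): FDFT1, squalene synthase (−0.20, SE 0.05, adjusted p = 0.0207), and MSMO1, a methylsterol oxidase (−0.26, SE 0.07, adjusted p = 0.0273). FDPS (−0.03, adjusted p = 0.838) and HMGCS1 (−0.16, adjusted p = 0.148) were not called. Of 8 epithelial markers 4 were called lower by either adjustment (adjusted p = 0.000257, but 0.145 by estimated correlation): among them EPCAM (−0.48, adjusted p = 0.00457), KRT8 (−0.29, adjusted p = 0.000746) and KRT18 (−0.22, adjusted p = 0.00449), of which the last 2 overlap on opposite strands. The polarity gene LLGL2 was at 8.92 ± 0.785 against 16.2 ± 0.584 CPM (−0.86, SE 0.12, adjusted p = 7.19e-05). DHRS3 (−0.93, SE 0.20, adjusted p = 0.00593), DHRS4L2 (−0.89, SE 0.17, adjusted p = 0.00151), a copy of DHRS4, and PTHLH, which encodes the parathyroid hormone-related protein of bone metastasis (−1.55, SE 0.43, adjusted p = 0.0265), were lower. PTHLH was scarce, at 0.428 ± 0.112 against 1.27 ± 0.318 CPM. FDFT1 was no longer called without BITC+ZA library 2 (adjusted p = 0.096) or 3 (0.0822), MSMO1 without ZA library 1 (0.0604), BITC+ZA library 2 (0.0875) or 3 (0.168) or after GC and length correction (−0.14, adjusted p = 0.0582), DHRS3 without BITC+ZA library 3 (0.0554), and PTHLH without ZA library 3 (0.0751) or BITC+ZA library 1 (0.0965), 2 (0.0614) or 3 (0.115).

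Of 5 metallothionein and zinc export genes 3 were called lower by either adjustment (adjusted p = 2.58e-07, and 0.00769 by estimated correlation), with MT2A at 436 ± 26.5 against 564 ± 24.7 CPM (−0.37, SE 0.05, adjusted p = 3.52e-05) and MT1E lower as well (−0.60, SE 0.10, adjusted p = 0.00457). Of 19 interferon-stimulated genes 4 were called lower by either adjustment (adjusted p = 0.000257, and 0.0248 by estimated correlation), with IFIT1 at 46.9 ± 1.86 against 64.1 ± 4.70 CPM (−0.45, SE 0.07, adjusted p = 0.000101). Of 39 ribosomal protein transcripts 21 were called lower, or 29 over the list alone (adjusted p = 6.94e-17, and 0.0409 by estimated correlation). Of 13 mitochondrially encoded transcripts 1 was called higher by either adjustment (adjusted p = 0.00104, but 0.504 by estimated correlation, and 0.156 at the preset correlation without ZA library 3). The mitochondrial share was 4.83 ± 0.0836% against 4.25 ± 0.604%. In all, 1039 genes were called, 495 higher and 544 lower, with a median fold size of 1.21. The share higher was 47.6%, and 37.0% and 36.4% by limma on the 2 FPKM scales. In the fit to the 2 groups only it was 71.6% (164 higher, 65 lower), and over genes with an FPKM of at least 5 61.5% (489 higher, 306 lower). The groups did not overlap for 1011 called genes and for 23.7% of all tested, where chance gives 10%. The number called was 1940 without ZA library 1, and 599, 390 and 367 without BITC+ZA libraries 1, 2 and 3.

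**Figure D4:**
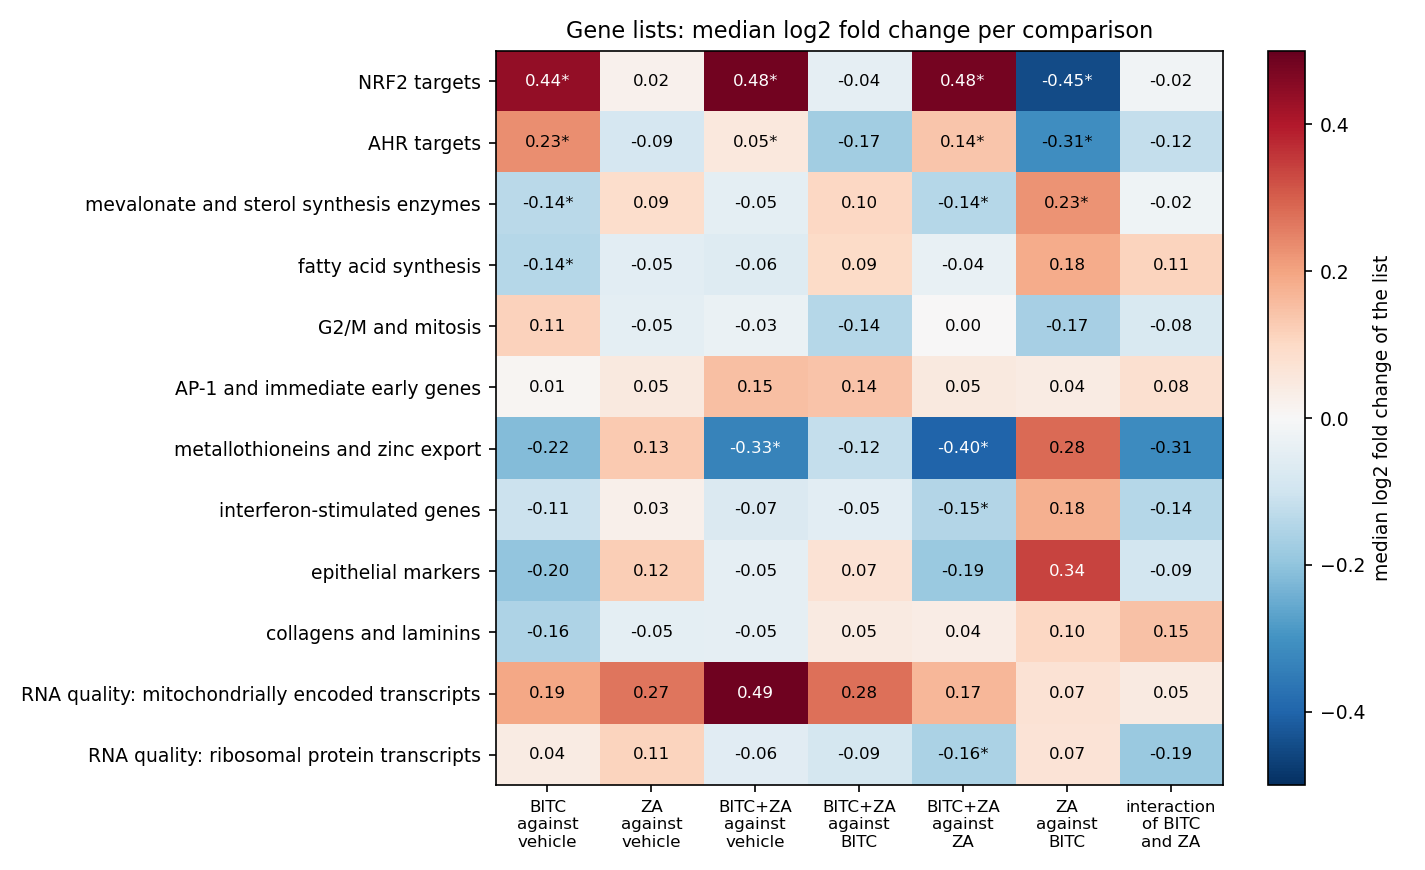
Each cell gives the median log2 fold change of 1 of 12 gene lists (vertical) in 1 of the 7 comparisons (horizontal), and a star marks an adjusted p below 0.05 by camera with an estimated correlation. NRF2 targets are starred in every comparison of a group with BITC against one without, and no list is starred in ZA against vehicle, BITC+ZA against BITC or the interaction.

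A direct comparison of ZA with BITC set the single compounds against each other. SLC7A11 was at 105 ± 8.31 CPM in ZA and 205 ± 11.1 in BITC (−0.96, SE 0.06, adjusted p = 7.74e-12). NQO1 (−0.77, SE 0.04, adjusted p = 3.83e-12), FTL (−0.64, SE 0.04, adjusted p = 9.59e-12), AKR1C3 (−0.86, SE 0.11, adjusted p = 1.2e-05), PIR (−0.82, SE 0.15, adjusted p = 0.0014) and GCLM (−0.45, SE 0.05, adjusted p = 1.54e-06) were lower in ZA too. Of the 26 NRF2 targets 19 were called lower in ZA, or 22 over the list alone (adjusted p = 5.8e-55, and 9.2e-05 by estimated correlation), and of 5 AHR targets 4 by either adjustment (adjusted p = 8.61e-11, and 0.00183 by estimated correlation). HMOX1 was not called (−0.14, SE 0.14, adjusted p = 0.569), but was called lower after GC and length correction (−0.33, adjusted p = 0.0446). RHOB was at 37.9 ± 1.04 CPM in ZA and 21.6 ± 0.780 in BITC (0.81, SE 0.07, adjusted p = 7.94e-08), and FAM89B was higher in ZA (1.62, SE 0.32, adjusted p = 0.00271).

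Of 20 mevalonate and sterol enzymes 11 were called higher in ZA than in BITC, or 13 over the list alone (adjusted p = 9.86e-08, and 0.00286 by estimated correlation). LSS, lanosterol synthase, was at 141 ± 20.5 against 105 ± 1.76 CPM (0.43, SE 0.07, adjusted p = 0.000807), with DHCR7 (0.34, SE 0.07, adjusted p = 0.00268), FDPS (0.22, SE 0.06, adjusted p = 0.0293) and HMGCS1 (0.23, SE 0.06, adjusted p = 0.0229) also higher. Of 8 epithelial markers 6 were called higher, or 7 over the list alone (adjusted p = 2.25e-06, but 0.0886 by estimated correlation), including KRT8 (0.35, adjusted p = 0.000118) and KRT19 (0.35, adjusted p = 0.000981). Of 20 genes of G2/M and mitosis 10 were called lower, or 1 higher and 15 lower over the list alone (adjusted p = 3.13e-08, but 0.0618 by estimated correlation), with CENPF (−0.26, adjusted p = 0.000499) and KIF20A (−0.23, adjusted p = 0.00271) as examples. FDPS was no longer called without BITC library 1 (adjusted p = 0.144) or 2 (0.145) or ZA library 2 (0.109) or 3 (0.166) or after GC and length correction (0.15, adjusted p = 0.0578), and HMGCS1 without BITC library 1 (0.0866) or 2 (0.129) or ZA library 3 (0.11). Of 39 ribosomal protein transcripts 13 were called higher, or 17 higher and 1 lower over the list alone (adjusted p = 3.86e-05, but 0.262 by estimated correlation), and of 9 histone transcripts 2 lower by either adjustment (0.0294, but 0.113). The histone call was lost without BITC library 1 (0.0623) or ZA library 1 (0.172). In all, 1577 genes were called, 913 higher and 664 lower in ZA, with a median fold size of 1.22. The share higher was 57.9%, and 47.6% after GC and length correction, or 46.5% without ZA library 1 as well. In the fit to the 2 groups only it was 71.3% (129 higher, 52 lower). The groups did not overlap for 1209 called genes and for 21.2% of all tested, where chance gives 10%. The number called was 558 and 380 without BITC libraries 1 and 2, and 4525, 388 and 672 without ZA libraries 1, 2 and 3.

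The interaction asked whether the response to both compounds departed from the sum of the single responses on the log2 scale. CXCL8 was at 19.3 ± 0.839 CPM in vehicle, 34.4 ± 1.40 with BITC, 27.5 ± 3.43 with ZA and 23.6 ± 1.75 with both, an interaction of −1.05 (SE 0.13, adjusted p = 0.000153). The related chemokine gene CXCL1 was at 3.15 ± 0.129, 4.67 ± 0.811, 4.89 ± 0.233 and 3.21 ± 0.472 CPM in that order (−1.17, SE 0.26, adjusted p = 0.015). In the other direction, LAMA3 was at 58.3 ± 1.57, 47.2 ± 4.28, 46.2 ± 1.76 and 56.5 ± 3.55 CPM (0.59, SE 0.10, adjusted p = 0.0024). The histone methyltransferase gene KMT2D was at 82.2 ± 1.13, 64.3 ± 3.08, 63.4 ± 15.3 and 93.6 ± 3.69 CPM (0.91, SE 0.17, adjusted p = 0.0181). MICAL3 (0.73, SE 0.12, adjusted p = 0.0024), ZFHX3 (0.68, SE 0.11, adjusted p = 0.0024), HIC1 (0.77, SE 0.20, adjusted p = 0.03) and FAM219B (0.65, SE 0.17, adjusted p = 0.0393) were called above the sum. PI16 (−1.19, SE 0.29, adjusted p = 0.0257), COMMD6 (−0.85, SE 0.17, adjusted p = 0.0093) and PLGRKT (−0.71, SE 0.19, adjusted p = 0.0369) were called below it. CXCL1 was no longer called without BITC+ZA library 3 (adjusted p = 0.0644). KMT2D was lost without vehicle library 1 (0.0646) or 2 (0.0644), BITC library 1 (0.0722) or 3 (0.0521), or BITC+ZA library 2 (0.0588) or 3 (0.0661), and PI16 without the same 6 (0.0574 to 0.0808). HIC1 was lost without any vehicle or BITC library or without BITC+ZA library 2 or 3 (0.0542 to 0.11), PLGRKT without vehicle library 1 or 2 or any BITC or BITC+ZA library (0.0563 to 0.117), and FAM219B without any library other than those of ZA (0.051 to 0.111). After GC and length correction PLGRKT was lost (−0.53, adjusted p = 0.0834), and without ZA library 1 as well so was FAM219B (0.54, adjusted p = 0.0656).

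Of the 26 NRF2 targets 0 were called above the sum and 1 below, or 0 and 4 over the list alone, with no call for the list (adjusted p = 0.245, but 0.0305 without ZA library 1). NQO1 (−0.12, SE 0.06, adjusted p = 0.295), GCLM (−0.15, SE 0.07, adjusted p = 0.259) and HMOX1 (0.36, SE 0.19, adjusted p = 0.328) were not called. FDPS (0.10, SE 0.09, adjusted p = 0.615) and HMGCS1 (−0.01, SE 0.09, adjusted p = 0.957) were not called either. Of 17 factors of bone metastasis 2 were called below the sum, CXCL8 and DKK1, a Wnt antagonist (−0.23, SE 0.06, adjusted p = 0.0497), or 4 over the list alone (adjusted p = 0.0266, but 0.217 by estimated correlation). The list call was lost without BITC library 2 (adjusted p = 0.0568) or ZA library 2 (0.0584), and that of DKK1 without any library other than ZA libraries 1 and 3 (0.0561 to 0.166). GC and length correction ended the calls of the list (0.0763) and of DKK1 (−0.06, adjusted p = 0.593). Of 18 collagens and laminins 3 were called above the sum by either adjustment (adjusted p = 0.00354, but 0.277 by estimated correlation, and 0.592 after GC and length correction). Of 39 ribosomal protein transcripts 13 were called below the sum, or 23 over the list alone (adjusted p = 3.22e-13, but 0.217 by estimated correlation), with RPS19 at −0.43 (SE 0.07, adjusted p = 0.00121), which was not called after GC and length correction (−0.48, adjusted p = 0.0727). Mitochondrially encoded transcripts had no call as a list (adjusted p = 0.944), but were called above the sum without ZA library 1 (0.000102) or after GC and length correction (0.00665).

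In total 425 genes were called for the interaction, 196 above and 229 below the sum, with a median fold size of 1.31. The share above was 46.1%, and 35.1% after GC and length correction. Most calls were above the sum without vehicle library 1 (69 above, 50 below, 58.0% above) or BITC library 2 (166 and 116, 58.9%), and over genes with an FPKM of at least 5 (236 and 117, 66.9%). On FPKM values limma called only 16 genes on log2(FPKM + 1) and 27 on log2(FPKM + 0.1). The count was 119, 134 and 248 without vehicle libraries 1, 2 and 3, 96, 282 and 263 without those of BITC, 854, 675 and 921 without those of ZA, and 265, 151 and 104 without those of BITC+ZA.

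The responses against vehicle shared some genes. BITC and BITC+ZA had 54 genes called higher in both and 61 lower in both, against 2.88 and 3.62 for independent lists, and 1 gene in opposite directions. ZA and BITC+ZA shared 17 higher and 7 lower, against 1.32 and 2.56, with 1 opposite, and BITC and ZA shared 2 higher and 11 lower, against 0.411 and 1.06, with 0 opposite. Unchanged groups simulated 20 times against a shared vehicle group gave at most 2 calls each. Their genes of smallest p were therefore taken in the observed numbers, a step chosen after seeing the results. These shared on average 35.4 higher and 33 lower (at most 43 and 44) for BITC and BITC+ZA, 18.75 and 26.85 (24 and 33) for ZA and BITC+ZA, and 10.25 and 15.4 (14 and 23) for BITC and ZA. By this count only the sharing of BITC and BITC+ZA was above the simulations. For the pairs in the same order, the covariance of log2 fold changes was 0.0309, 0.0320 and 0.0250. Simulated means were 0.0237, 0.0240 and 0.0236, and the highest 0.0257, 0.0257 and 0.0248. All 3 were above these, but by correlation (0.382, 0.425 and 0.356 against simulated means of 0.493, 0.496 and 0.490) all were below. Shared GC content trends and vehicle spread may add to the covariance, so it does not show a shared response. Part of the shared calls may come from the 3 shared vehicle libraries, too few to be split.

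The authors' deposited tables, computed with DESeq2 on the 6 libraries of each comparison, list other numbers of genes with an adjusted p below 0.05. In the authors' deposited table for BITC against vehicle these were 922 (420 higher, 502 lower), for ZA against vehicle 98 (19 and 79) and for BITC+ZA against vehicle 1699 (705 and 994). The authors' deposited tables gave 2920 (1265 and 1655) for BITC+ZA against BITC, 398 (210 and 188) for BITC+ZA against ZA and 594 (367 and 227) for ZA against BITC.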

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

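The tests of ZA library 1 for a vehicle library and for a batch across the groups, that of a GC content trend among long transcripts, the interval around the share of non-coding transcripts, and the comparison of FPKM values with counts over exon length were chosen only after the results had been seen. The test on NRF2 targets was written down beforehand for BITC in the dish, and its reading as a test of the label came afterwards. The other tests of this part were written down beforehand.

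The interaction term called 425 genes whose response to BITC differed with and without ZA. The genes named for it were above the sum for KMT2D (0.91), HIC1 (0.77), MICAL3 (0.73), ZFHX3 (0.68) and FAM219B (0.65), and below it for PI16 (−1.19), CXCL1 (−1.17), CXCL8 (−1.05), COMMD6 (−0.85) and PLGRKT (−0.71), each on the log2 scale. On FPKM values limma called only 16 genes on log2(FPKM + 1) and 27 on log2(FPKM + 0.1). Among 100 groupings of the 12 libraries 4, the real one included, called as many genes, and the highest other called 2668, which points to a structure of the samples. Fewer than 5 had been set beforehand to count against chance. That bound was wrong by design, since every other grouping mixed libraries of different treatments and so moved treatment effects into the spread or the contrast, and whether chance can be excluded stays open. Without vehicle libraries 1, 2 and 3 the calls numbered 119, 134 and 248, without those of BITC 96, 282 and 263, of ZA 854, 675 and 921, and of BITC+ZA 265, 151 and 104.

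The calls of CXCL8, MICAL3, ZFHX3 and COMMD6 were kept without any 1 library, but by limma on the 2 FPKM scales those of MICAL3 (adjusted p = 0.107 on both), ZFHX3 (0.1 and 0.0964) and COMMD6 (0.0666 and 0.0628) were lost. CXCL1 was lost without BITC+ZA library 3 (adjusted p = 0.0644). KMT2D and PI16 were lost without vehicle library 1 or 2, BITC library 1 or 3, or BITC+ZA library 2 or 3 (0.0521 to 0.0808). HIC1 was lost without any vehicle or BITC library or BITC+ZA library 2 or 3 (0.0542 to 0.11), PLGRKT without vehicle library 1 or 2 or any BITC or BITC+ZA library (0.0563 to 0.117), and FAM219B without any library other than those of ZA (0.051 to 0.111).

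The 6 libraries of a pairwise comparison can be split in 10 ways, too few for a share under 0.05. All but the real split mixed treatments, as for the interaction, so chance stays open. The real split gave 266 calls for BITC against vehicle, 732 for BITC+ZA against vehicle and 2205 for BITC+ZA against BITC (highest other 0 in each), and 1039 for BITC+ZA against ZA (highest other 2). In these 4 only the real split gave as many. In ZA against vehicle 2 of 10 did: 159 genes for the real split and 214 for ZA library 1 with vehicle libraries 1 and 3. In ZA against BITC 2 of 10 did too, with 1577 for the real split and 2386 for ZA library 1 with BITC libraries 1 and 2.

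ZA library 1 lay apart from ZA libraries 2 and 3, with a chi-square per gene of 16.9 and 15.1 against 3.18 between those. The GC content and length trend explains part at most. Correcting it moved the mean correlation of deviations with ZA libraries 2 and 3 from −0.252 to −0.0894, below every other group (lowest 0.0828). RHOB had a log2 ratio of 0.715 to the vehicle mean (36.8 CPM against 20.8 to 23.3 in vehicle and BITC libraries). It was picked from calls with this library, so a vehicle library stays open. A median change of −0.0427 in NRF2 targets (at least 0.442 in BITC and BITC+ZA) argues against those 2 groups. Slopes ranging by at most 0.0804 within another group argue against a batch. Over 881 genes this library had a slope of 0.0543 (vehicle −0.0836 to 0.0598) on the change of the other ZA libraries. This meets the outcome written beforehand for a mislabelled sample (under 0.25). A vehicle library, an outside sample and a ZA dish that differed cannot be told apart. No value here identifies the dish, and no biological explanation was tested.

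Non-coding transcripts called in BITC+ZA against vehicle were 93.7% higher (74 higher, 5 lower). The GC content and length trend stays open: after its correction without ZA library 1 80.9% were still higher (83.2% before it), past the bound of 80% set beforehand against it, but by less than the spread (95% interval 74.0 to 86.6%), and processed pseudogenes were mostly lower, with 7 higher and 18 lower (10 and 13 before it). Genomic DNA carried into the libraries may contribute: over 54 genes of gene families silent in this cell type the counts were 445 against 386, a ratio of 1.21 (95% interval 1.05 to 1.39, counting error only) beside 1.11 for the antisense share, although single libraries overlapped (7.20 to 10.3 CPM against 6.74 to 8.06). Unspliced nuclear RNA predicts a positive relation of the change with genomic span over exon length, and the partial rank correlation over 10737 genes was −0.215, below the bound of 0.1 set beforehand against it; it stays open because 100% of the FPKM values equal the count over the exon length within 1%, up to 1 factor per library, so that the counts may hold no intron reads and the test then says nothing. With 1 factor for all libraries, as this check was first run, only part of the values did, and a biological response to the combination was not tested.

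Long transcripts were lower in ZA against vehicle, with a median exon length of 12510.5 bases among genes called lower and 2155 among those called higher. A GC content trend alone is argued against, since with GC content held the rank correlation of the change with exon length was −0.240 or stronger in each ZA library over 10737 genes. Loss of long RNA may be a source: with genomic span held too, the correlation was still −0.106 or stronger in each ZA library, though BITC libraries 1 (−0.137) and 3 (−0.131) showed as much and the BITC+ZA libraries had the opposite sign (0.117 to 0.159). Lower transcription of long genes, the biological alternative, predicts a relation with genomic span, which was −0.0823 in ZA library 1, −0.228 in ZA library 2 and −0.165 in ZA library 3, and −0.205, −0.166 and −0.175 in the BITC+ZA libraries and −0.109 in BITC library 3, against −0.0141 to 0.0156 in vehicle; it stays open because 1 library falls short of the bound of −0.1 set beforehand, and genes are not independent replicates here.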

How the results depend on the processing

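The GC and length correction, with and without ZA library 1, was chosen after the results had been seen, all other settings before. No called gene named in the text changed direction in any setting that tested it. Calls were kept in all such settings for 14 of 22 called genes for BITC against vehicle, 1 of 14 for ZA against vehicle (RHOB), 23 of 29 for BITC+ZA against vehicle, 11 of 15 for BITC+ZA against BITC, 13 of 22 for BITC+ZA against ZA, 15 of 22 for ZA against BITC and 1 of 16 for the interaction (CXCL8).

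Median-of-ratios size factors, an FPKM of at least 5 and protein-coding genes only moved no count of calls by more than 1.5 times. Without a filter on low counts 494 genes were called for BITC against vehicle, 395 for ZA against vehicle and 706 for the interaction. The DESeq2 Wald test called 460 for ZA against vehicle and 719 for the interaction. On log2(FPKM + 1) limma called 141 for BITC against vehicle, 1 for ZA against vehicle, 630 for BITC+ZA against ZA, 895 for ZA against BITC and 16 for the interaction, and on log2(FPKM + 0.1) 138, 6, 627, 895 and 27. A fit to the libraries of the 2 groups only called 1397 for BITC against vehicle, 1 for ZA against vehicle, 2793 for BITC+ZA against vehicle, 3979 for BITC+ZA against BITC, 229 for BITC+ZA against ZA and 181 for ZA against BITC; it uses fewer samples and, for the comparisons without ZA, leaves out the spread of the ZA libraries. GC and length correction called 672 for BITC against vehicle, 370 for ZA against vehicle, 1165 for BITC+ZA against vehicle, 1287 for BITC+ZA against BITC and 1624 for BITC+ZA against ZA. Without ZA library 1 as well, it called 1266, 881 and 1691 against vehicle in that order, 1636 for BITC+ZA against ZA and 2402 for ZA against BITC. With an estimated correlation the calls of gene lists over the 7 comparisons went from 75 to 17. In the order of the report the correction alone kept 243 of 266, 100 of 159, 645 of 732, 802 of 2205, 851 of 1039, 788 of 1577 and 250 of 425 calls. Without a filter the share higher was 44.6% for ZA against vehicle. The cause was not tested.

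Leaving out each library in turn gave 102 to 1496 calls for BITC against vehicle, 1 to 2489 for ZA against vehicle, 288 to 2234 for BITC+ZA against vehicle, 525 to 4116 for BITC+ZA against BITC, 367 to 1940 for BITC+ZA against ZA, 380 to 4525 for ZA against BITC and 96 to 921 for the interaction. The highest came without ZA library 1, except for the interaction, where it came without ZA library 3.

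The replicate number as a block gave 315 calls for BITC against vehicle, 219 for ZA against vehicle, 842 for BITC+ZA against vehicle, 2533 for BITC+ZA against BITC, 1161 for BITC+ZA against ZA, 1785 for ZA against BITC and 563 for the interaction. The numbers did not clearly pair the libraries: the correlation of deviations over 18 same-numbered pairs was −0.19 to 0.14 (median 0.02), and 5 pairs exceeded 0.1. Of the 12 libraries 7 correlated best with their own number. The block ended the calls of HMOX1 (adjusted p = 0.0514) and MT1E (0.072) for BITC+ZA against vehicle and no other call of a gene or list named in the text.

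Of the named genes, limma on both FPKM scales and the fit to the 2 groups only each ended the calls of the 13 other than RHOB for ZA against vehicle. On both scales limma ended those of LLGL2, DHCR7, CCNB1 and CYP1B1 for BITC against vehicle, HMOX1 for BITC+ZA against vehicle, FDPS for BITC+ZA against BITC, MSMO1, COX7A2, NDUFA4 and HMOX1 for BITC+ZA against ZA, and TUBB2A and FDPS for ZA against BITC. On log2(FPKM + 1) DHRS3 for BITC+ZA against vehicle and all named interaction genes but CXCL8, CXCL1 and RPS19 were lost, and on log2(FPKM + 0.1) TUBA3D for BITC+ZA against BITC and the same interaction genes except PSMB1. The fit to 2 groups ended FDFT1, MSMO1, PTHLH, KRT18, ATP5F1C, COX7A2, NDUFA4 and HMOX1 for BITC+ZA against ZA, and TUBB6, TUBB2A, KIF20A, ISG15, FDPS and HMGCS1 for ZA against BITC. An FPKM of at least 5 ended MSMO1 and NDUFA4 for BITC+ZA against ZA and PLGRKT, PSMC4 and DKK1 for the interaction, and size factors or protein-coding genes only ended PSMC4 and DKK1. FDPS was lost and HMOX1 gained for BITC+ZA against BITC without a filter, HMOX1 was gained there with 2 groups only, and NQO1 by limma on both scales. GC and length correction without ZA library 1 ended the calls of TUBA1A for ZA against BITC (0.33 against 0.39, adjusted p = 0.0929) and of PSMC4 for the interaction (−0.16 against −0.25, adjusted p = 0.0639).

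Values close to 0 of genes that were not called changed sign. Over the libraries left out, HMOX1 ran from −0.0109 to 0.21 for BITC against vehicle, from −0.15 to 0.13 for ZA against vehicle and from −0.26 to 0.0126 for ZA against BITC. GCLM ran from −0.065 to 0.000246 for ZA against vehicle, FDPS from −0.089 to 0.0214 for BITC+ZA against ZA, and HMGCS1 from −0.0593 to 0.0269 for the interaction. With an FPKM of at least 5, FDPS was at 0.00273 for BITC+ZA against ZA and HMGCS1 at 0.028 for the interaction. After GC and length correction HMGCS1 was at 0.00603 for BITC+ZA against vehicle and 0.11 for the interaction (0.00594 and 0.0788 without ZA library 1). GCLM was at 0.0145 for ZA against vehicle with the correction and without ZA library 1. Mitochondrially encoded transcripts, not called for the interaction, changed direction without a filter (adjusted p = 0.915), by DESeq2 (0.997), without vehicle library 1 (0.964), and without 5 other libraries (0.373 to 0.959); without ZA library 1 they were called above it (0.000102).

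Among lists, GC and length correction reversed 3 directions, none with a call afterwards: for ZA against vehicle NRF2 targets (adjusted p = 0.605) and AP-1 genes (0.716, and 0.458 without ZA library 1), and for ZA against BITC tubulins (0.871, and 0.41 without ZA library 1). By limma on both FPKM scales the lists of mevalonate enzymes, YAP targets and AP-1 genes (ZA against vehicle), tubulins (ZA against BITC) and bone metastasis factors (interaction) had no call, nor had mesenchymal markers for BITC+ZA against vehicle, which were lost over protein-coding genes only as well. An FPKM of at least 5 ended the calls of mevalonate enzymes for ZA against vehicle, interferon-stimulated genes and mesenchymal markers for BITC+ZA against vehicle, ribosomal protein transcripts for BITC+ZA against BITC, tubulins for ZA against BITC and bone metastasis factors for the interaction, and of histone transcripts for BITC against vehicle, BITC+ZA against vehicle and ZA against BITC. Ribosomal protein transcripts for BITC+ZA against vehicle were lost with it and over protein-coding genes only. No filter ended bone metastasis factors for the interaction, and 2 groups only the AP-1 list for ZA against vehicle and histone transcripts for BITC+ZA against vehicle. The AP-1 list lost its call for BITC+ZA against BITC with GC and length correction and without ZA library 1 (0.0528), and so did interferon-stimulated genes for ZA against BITC (0.0889) and collagens and laminins for the interaction (0.714). The cause was not tested.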

Other observations

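The comparisons and gene lists of this part were planned, and the tests of the authors' adjusted p-values and of the FPKM totals were chosen after these had been seen. The single compounds also differed in interferon-stimulated genes: of 19 tested, 6 were called higher in ZA than in BITC and 1 lower, or 7 and 1 over the list alone (adjusted p = 0.0263, but 0.113 by estimated correlation, and 0.129 at the preset correlation without ZA library 1). IFIT1 was at 64.1 ± 4.70 CPM in ZA and 50.7 ± 1.93 in BITC (log2 fold change 0.34, SE 0.07, adjusted p = 0.0024), IFIT2 at 60.6 ± 2.75 and 48.0 ± 1.71 (0.34, SE 0.07, adjusted p = 0.00502), and ISG15, a ubiquitin-like modifier, at 101 ± 9.29 and 82.1 ± 2.64 (0.30, SE 0.06, adjusted p = 0.00295). Of 11 tubulins 3 were called higher in ZA by either adjustment (adjusted p = 0.0294, but 0.37 by estimated correlation): TUBA1A (0.39, SE 0.07, adjusted p = 0.00193), TUBB6 (0.22, SE 0.05, adjusted p = 0.00686) and TUBB2A (0.25, SE 0.07, adjusted p = 0.0337). After GC and length correction the tubulin list had no call (0.871), and ISG15 (0.04, adjusted p = 0.701), TUBB6 (0.06, adjusted p = 0.236) and TUBB2A (0.06, adjusted p = 0.63) were no longer called. The tubulin list lost its call without BITC library 2 (adjusted p = 0.138) or ZA library 1 (0.0612). TUBB6 was lost without BITC library 2 (0.065) or ZA library 2 (0.0526), and TUBB2A without BITC library 2 (0.172) or 3 (0.0956), ZA library 2 (0.0754) or 3 (0.258), or BITC+ZA library 3 (0.0506).

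Of 31 nuclear-encoded genes of the respiratory chain 6 were called lower in BITC+ZA than in ZA, or 11 over the list alone (adjusted p = 0.000201, but 0.101 by estimated correlation). They included ATP5F1C, of the ATP synthase (−0.26, SE 0.05, adjusted p = 0.00383), COX7A2, of cytochrome c oxidase (−0.26, SE 0.07, adjusted p = 0.0164), and NDUFA4 (−0.22, SE 0.06, adjusted p = 0.03). COX7A2 was no longer called without BITC+ZA library 1 (0.0727), 2 (0.0571) or 3 (0.0506), and NDUFA4 without BITC library 2 (0.053), ZA library 1 (0.0543) or BITC+ZA library 1 (0.139) or 2 (0.0935). After GC and length correction neither COX7A2 (−0.14, adjusted p = 0.0505) nor NDUFA4 (−0.12, adjusted p = 0.108) was called. Of 31 proteasome subunits 3 were called below the sum in the interaction, or 9 over the list alone (adjusted p = 0.000207, but 0.239 by estimated correlation). PSMB1 was at 210.1 ± 2.07 CPM in vehicle, 228 ± 4.25 with BITC, 236 ± 10.1 with ZA and 209 ± 0.581 with both (−0.29, SE 0.06, adjusted p = 0.0142), PSMB3 gave −0.30 (SE 0.07, adjusted p = 0.0201) and PSMC4 −0.25 (SE 0.07, adjusted p = 0.0477). PSMB1 was lost after GC and length correction (−0.11, adjusted p = 0.239) and without vehicle library 1 (0.0513), PSMB3 without vehicle library 1 (0.0836), BITC library 1 (0.0861) or BITC+ZA library 3 (0.0842), and PSMC4 without vehicle library 1 (0.134), 2 (0.108) or 3 (0.0795), BITC library 1 (0.0844), 2 (0.0835) or 3 (0.104), or BITC+ZA library 1 (0.0648), 2 (0.103) or 3 (0.147). Targets of ATF4 (21 tested) and p53 (14), autophagy genes (20) and genes of G1/S (18) had no camera call in any of the 7 comparisons, and neither had markers of luminal epithelium (4) or fibroblasts (3).

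In the authors' deposited tables an adjusted p of 1 goes with low counts. In the table for ZA against vehicle 20201 of 24809 genes (81.4%) have an adjusted p of 1, and these are the genes whose mean normalized count lies below a boundary of 862. Among them is RHOB, with a p of 9.93e-13 in the authors' deposited table and an adjusted p of 1. The authors' deposited table gives an adjusted p of 1 also for RAPH1 (p = 1.82e-06), TOMM7 (1.38e-05), MICAL3 (3.24e-05) and CXCL8 (7.73e-05). The boundary lay at 127 for BITC against vehicle, 36.5 for BITC+ZA against vehicle, 97.4 for ZA against BITC, 35.5 for BITC+ZA against BITC and 197 for BITC+ZA against ZA, with 1 gene above it in each of the last 4 tables. In every table the other adjusted p-values equal a Benjamini-Hochberg adjustment over the genes above the boundary. An adjustment over all genes of a table would call 674 genes for BITC against vehicle (922 in the authors' deposited table), 39 for ZA against vehicle (98) and 1321 for BITC+ZA against vehicle (1699).

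The totals implied by the FPKM values exceeded the summed gene counts by 2.72 to 3.28% in the BITC+ZA libraries and by 1.65 and 1.49% in ZA libraries 2 and 3, against 0.0918 to 0.587% in vehicle, −0.0136 to 0.620% in BITC and −0.0363% in ZA library 1.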
